A study of Homo sapiens with 36 samples.

How the data were processed

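Total RNA from the 3 cell lines was taken 24 h after treatment and measured on 36 arrays of Illumina BeadChips, 12 groups of 3 arrays. Per the labels, RNA was purified with RNeasy Plus columns and amplified with the Ambion MessageAmp kit into biotinylated cRNA. The bead intensities were exported with BeadStudio, per the labels, whose version is not given in the sources used here. The deposited scanner table holds mean bead intensities on a linear scale that the authors had neither background-corrected nor normalized between arrays. Beside each intensity, the deposited scanner table gives a detection p-value, and how BeadStudio computed it is not given in the sources used here. A second deposited table holds intensities that the authors normalized between arrays by a method not given in the sources used here, on a linear scale without background subtraction. The columns of the scanner table are named by group and replicate number. Each of the 36 matched best a column of its own group in the second table (Pearson's r across 36045 probes 0.962 to 0.999), but none the column with its own replicate number, and whole replicate sets matched together. The scanner table's own numbering was used.

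The scanner table has 47323 probes, of which 6 lack a value and were left out where they lack it, and 99 are absent from the second table. Probes were assigned to genes with the annotation given for the series, which lists 1 gene for 30107 probes, several for 8 and none for 17208. Intensities were background-corrected and quantile normalized with neqc of limma (background inferred from the detection p-values, offset 16) and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 arrays were kept (36065), and the probe with the highest mean stood for each gene symbol, giving 16897 genes, 5074 of them with several probes. Probes of 1 gene were called in opposite directions for CUL4A (Het-1A, MS-275), ANTXR1, COL4A6 and ERLIN2 (OE21, both drugs), DSE and TGM2 (OE33, MS-275) and DSE, MYF6, SRI, TFAP2A, TGM2 and TSPYL2 (OE33, both drugs). Arrays of a group correlated with a Pearson's r of 0.972 to 0.991 across genes, which are not independent replicates. Several arrays of replicate set 2 stood apart from their groups on the main axis of within-group variation (24.8% of it), and cell lines made up the main axes over all arrays.

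A model of 12 group means was fitted with lmFit and eBayes with an intensity trend (24 residual and 7.12 prior degrees of freedom), and 26 contrasts were tested two-sided. They were each drug against DMSO, the combination against each drug and against the sum of both, the difference of each tumor line's response from that of Het-1A, and the tumor lines against Het-1A in DMSO. Adjusted p-values are Benjamini-Hochberg per contrast, with a threshold of 0.05. MS-275 and the combination share their DMSO arrays within a line. A fold against a group not detected on all 3 of its arrays is a lower bound, and a difference between responses with such a group is given without a size. Named genes followed 4 rules, and genes outside them are said to be chosen after their values were seen. For each drug comparison they were the 6 largest rises and 6 largest falls among called genes with a probe of exactly 1 gene, a symbol that is not a placeholder, and the same sign in each replicate set. For each list called or with members past the test, they were up to 4 members with the largest change. For the other contrasts they were the 4 largest each way, and the genes of the drug targets, of azacytidine handling and CDKN1A were always looked up. A further gene of that rule is not reported here.

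Gene lists were tested with camera (preset correlation 0.01) in 17 contrasts, 357 tests adjusted together, and again with an estimated correlation and with fry. The 21 lists were p53 targets, mitosis, DNA replication, DNA repair, histones, cancer-testis and germline genes, interferon response, chromatin regulators with HDACs and DNMTs, azacytidine metabolism, apoptosis, integrated stress, ribosome biogenesis, squamous, columnar, mesenchymal, leukocyte, endothelial and neuronal markers, immediate-early genes, NF-kappaB targets and cholesterol biosynthesis. The groups, contrasts, lists, naming rules and most alternatives were fixed before the data were examined. Of 73 called list tests, 22 held with an estimated correlation, 11 of 36 among the drug comparisons. Overlaps were tested one-sided with Fisher's exact test.

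The replicate numbers pair arrays, since all arrays with 1 number share an array identifier, read here as a chip or scan set. Whether the sets were also cultured separately is not given in the sources used here. Residuals of arrays with the same number had a median r of 0.27 across genes (198 pairs) and those with different numbers -0.14 (396 pairs). Within a line the median was 0.27 to 0.39, except in OE33 in set 2 (-0.053) and set 3 (0.13). Alternatives were a fit with the replicate set as a block, no background correction, median scaling, the submitters' normalized values, no filter, a stricter filter (detection p under 0.01 on all 3 arrays of a group), fits of the compared lines alone, every probe, each array left out, and values within each replicate set. A left-out array leaves 2 in its group, and the spread is pooled over all groups. The pipeline was tested on simulated data before use. Tools were R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.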

Results

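Gene expression was measured on 36 Illumina BeadChip arrays of 3 human esophageal cell lines, in a study that asked how normal and tumor cells of the esophagus respond to inhibitors of histone deacetylases (HDACs), enzymes that remove acetyl groups from histones. Het-1A is an esophageal epithelial line that the labels call non-neoplastic and that was immortalized with SV40 large T antigen, a viral protein that binds p53. OE21 came from a squamous cell carcinoma of the mid esophagus and OE33 from an adenocarcinoma of the lower esophagus with Barrett's metaplasia. Each line was treated for 24 h with the solvent DMSO, with 50 µM azacytidine (AZA, a cytidine analog that traps DNA methyltransferases), with 0.5 µM MS-275 (also known as entinostat, an inhibitor of class I HDACs), or with both drugs. Every one of the 12 groups held 3 arrays, and the series describes them as biological triplicates. Between 45.9% and 51.3% of the probes on an array were detected above background, and the median probe intensity ranged from 93.3 to 109.9. Changes are log2 changes with their standard error (change ± SE, n = 3 arrays per group), and a call means an adjusted p under 0.05 in limma among 16897 genes. Arrays with 1 replicate number share an array identifier, read here as a chip, and form replicate sets 1, 2 and 3. A list's median is that of its genes' log2 changes, over all arrays and then within sets 1, 2 and 3, and where a group lay at background the fold is given as a lower bound (at least).

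In DMSO, OE21 differed from Het-1A in squamous, interferon and mesenchymal genes, among others. The aldo-keto reductases AKR1C2 (at least 606-fold) and AKR1C3 (at least 383-fold), the caveolar coat gene CAV1 (at least 487-fold, adjusted p = 3.51e-27) and the squamous keratin gene KRT6C (at least 350.0-fold) were higher in OE21. The smooth muscle genes TAGLN (at least 461-fold) and ACTG2 (at least 229-fold), SRGN (at least 294-fold) and the matricellular gene CCN2 (-7.50 ± 0.32, adjusted p = 3.31e-19) were lower. Of the squamous differentiation list, 18 of 21 genes were higher in OE21 (18 adjusted over the list alone), among them the basal keratin gene KRT5 (at least 303-fold) and the suprabasal KRT13 (at least 183-fold). Their median was 5.37 (sets 5.84, 5.04 and 5.18, adjusted p = 4.24e-21). Of the interferon response list, 27 of 29 genes were higher and 1 was lower (27 and 1 adjusted over the list alone), with IFI44L (5.44 ± 0.26) the furthest. Their median was 1.80 (sets 1.83, 1.85 and 1.76, adjusted p = 2.67e-15). Mesenchymal and fibroblast markers were lower in OE21, 14 of 19 genes (14 adjusted over the list alone). Their median was -2.80 (sets -2.73, -2.86 and -2.81, adjusted p = 6.28e-10), or -1.27 with no background correction and -1.41 with the submitters' values. Called medians were 0.65 and 0.73 times as large at the median under these 2 alternatives, which subtract no background. Mitosis genes were lower in 18 of 24 cases, 21 adjusted over the list alone, with a median of -1.10 (sets -1.10, -1.09 and -1.12, adjusted p = 5.89e-07, but 0.156 with an estimated correlation). Integrated stress genes were higher in 11 of 21 cases and lower in 1, 13 and 2 adjusted over the list alone, with a median of 0.69 (sets 0.78, 0.74 and 0.76, adjusted p = 0.000168, but 0.0973 with an estimated correlation). limma called 2946 genes higher and 3482 lower in OE21.

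OE33 in DMSO had lower levels of mesenchymal genes than Het-1A. The metalloproteinase gene MMP7 (at least 576-fold), KLK6 (at least 524-fold), CAPZA2 (at least 303-fold) and CAV1 (at least 293-fold, adjusted p = 2.46e-26) were higher. The secretory gene AGR2 (4.61 ± 0.27), the epithelial adhesion gene EPCAM (4.24 ± 0.20) and the intestinal transcription factor gene CDX2 (at least 9.09-fold) were higher as well, with 7 of 20 columnar markers higher and 1 lower and the list as a whole not called. The galectin gene LGALS1 (-8.86 ± 0.34), TAGLN (at least 454-fold), SRGN (at least 303-fold) and the intermediate filament gene VIM (-7.32 ± 0.17, adjusted p = 6.78e-26) were lower, and so was the N-cadherin gene CDH2 (at least 309-fold). Mesenchymal and fibroblast markers were lower in OE33, 15 of 19 genes (15 adjusted over the list alone). Their median was -3.44 (sets -3.48, -3.11 and -4.07, adjusted p = 8.76e-15). Interferon response genes lay on the opposite side of Het-1A from those in OE21, with 20 of 29 lower and 1 higher (20 and 1 adjusted over the list alone), among them BST2 (-5.87 ± 0.25), a restriction factor that tethers virions. Their median was -1.17 (sets -1.03, -1.45 and -1.29, adjusted p = 1.48e-07, but 0.127 with an estimated correlation). Of mitosis genes 16 of 24 were lower, 16 adjusted over the list alone, with a median of -0.60 (sets -0.73, -0.49 and -0.68, adjusted p = 0.000847, but 0.368 with an estimated correlation). Of neuronal genes 13 of 26 were lower and 2 higher, 13 and 2 adjusted over the list alone, with a median of -0.39 (sets -0.22, -0.41 and -0.56, adjusted p = 0.00703, but 0.0701 with an estimated correlation). Ribosome biogenesis genes were higher in 8 of 21 cases and lower in 1, 8 and 1 adjusted over the list alone, with a median of 0.44 (sets 0.41, 0.53 and 0.33, adjusted p = 0.0465, but 0.219 with an estimated correlation). The ribosome biogenesis call was lost without Het-1A DMSO 1, 2 or 3 or OE33 DMSO 2 or 3 (adjusted p = 0.0528 to 0.0719). limma called 3130 genes higher and 3373 lower in OE33.

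AZA alone moved a group of inflammatory genes in Het-1A without any single gene passing the test. Genes controlled by NF-kappaB, a transcription factor of inflammation, shifted downward together, with a median of -0.42 (sets -0.43, -0.44 and -0.42, adjusted p = 6.8e-14), or -0.16 with no background correction and -0.19 with the submitters' values. Over all genes 0 of 19 passed, while 3 did adjusted over the list alone. The 3 were the neutrophil chemokine genes CXCL1 (-0.88 ± 0.28) and CXCL8 (-0.75 ± 0.20) and the cytokine gene IL6 (-0.74 ± 0.20), named after their values were seen. The cell cycle inhibitor gene CDKN1A (0.20 ± 0.20) and the target of the drug, DNMT1 (-0.088 ± 0.25), did not pass. limma called 0 genes, with 416 at an unadjusted p under 0.05 where 845 would be expected with no effect. So few point to a conservative test, not to no effect. With the replicate set as a block 2 were called, and 4 without DMSO 1.

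MS-275 alone raised neuronal genes in Het-1A. The largest rises were in IL24 (3.02 ± 0.24), a cytokine gene, HLA-DMB (2.98 ± 0.20, adjusted p = 2.32e-11), which helps load peptides onto MHC class II, HPCAL4 (2.70 ± 0.20), of a neuronal calcium sensor family, CYP4F22 (at least 6.2-fold), a fatty acid hydroxylase of skin ceramide synthesis, CNTNAP2 (at least 5.42-fold), a neurexin family gene, and TAGLN3 (2.40 ± 0.20). HLA-DMB rose 7.89-fold and CDKN1A rose 2.64-fold (1.40 ± 0.20, adjusted p = 1.4e-05). The falls were smaller, led by HK2 (-1.24 ± 0.22), PER2 (-1.24 ± 0.30), RFLNA (-1.17 ± 0.29), LANCL2 (-1.16 ± 0.14, adjusted p = 6.09e-07), ZFX (-1.16 ± 0.33) and WASHC2C (-1.14 ± 0.28). Of neuronal genes, 9 of 26 genes rose (12 adjusted over the list alone), among them CRMP1 (2.02 ± 0.20), SYT11 (1.502 ± 0.21), KIF5C (1.43 ± 0.23) and SYN1 (1.35 ± 0.20). Their median was 0.40 (sets 0.55, 0.29 and 0.68, adjusted p = 6.28e-10), or 0.19 with no background correction, 0.23 with the submitters' values and 0.62 with the stricter filter. Of NF-kappaB targets, 5 of 19 genes rose (5 adjusted over the list alone), led by the interleukin genes IL1A (at least 3.61-fold) and IL6 (1.33 ± 0.20). Their median was 0.24 (sets 0.18, 0.37 and 0.29, adjusted p = 0.000587, but 0.085 with an estimated correlation). Of immediate-early genes, 4 of 21 genes rose (6 adjusted over the list alone), led by IER3 (1.20 ± 0.14). Their median was 0.43 (sets 0.45, 0.37 and 0.48, adjusted p = 0.000133, but 0.203 with an estimated correlation). Ribosome biogenesis genes lay lower with 0 of 21 past the test, also adjusted over the list alone. Their median was -0.25 (sets -0.30, -0.19 and -0.26, adjusted p = 0.00138, but 0.0542 with an estimated correlation). Columnar and intestinal markers lay higher (4 of 20 genes rose, 5 adjusted over the list alone), with the foregut transcription factor gene FOXA2 (at least 2.87-fold) and EPCAM (0.92 ± 0.20). Their median was 0.15 (sets 0.018, 0.24 and 0.23, adjusted p = 0.0329, but 0.0781 with an estimated correlation). Leukocyte markers lay higher (4 of 12 genes rose, 4 adjusted over the list alone), with the macrophage marker gene CD68 (1.03 ± 0.14) and CD14 (1.01 ± 0.21). Their median was 0.082 (sets 0.021, 0.41 and 0.22, adjusted p = 0.019, but 0.0814 with an estimated correlation). The nucleoside transporter gene SLC29A2 (at least 3.1-fold), the beta-tubulin gene TUBB2B (1.37 ± 0.20) and the endothelial adhesion gene ESAM (at least 2.09-fold) rose. limma called 778 genes higher and 188 lower with MS-275 in Het-1A, of which 313 and 12 changed at least 2-fold. The count was 1569 with the replicate set as a block and 531 without replicate set 2, and scaling by the median gave 538 higher and 461 lower. Calls were lost without 1 array for PER2 (without MS-275 1, adjusted p = 0.0632), RFLNA (without DMSO 1, adjusted p = 0.061), ZFX (without DMSO 1 or 2 or MS-275 1 or 2, adjusted p = 0.053 to 0.169) and WASHC2C (without MS-275 3, adjusted p = 0.0556). The columnar list lost its call without DMSO 2 or MS-275 2 (adjusted p = 0.0657 to 0.0995) and the leukocyte list without MS-275 2 (adjusted p = 0.0883).

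With both drugs, Het-1A again raised neuronal genes and lowered ribosome biogenesis genes. HLA-DMB (2.94 ± 0.20), HPCAL4 (2.47 ± 0.20), IL24 (2.45 ± 0.24) and CYP4F22 (at least 4.92-fold) rose, together with the prostaglandin synthase gene PTGS2 (at least 5.29-fold, adjusted p = 8.93e-08) and CA2 (2.36 ± 0.26). The largest falls were in SPAG7 (-1.43 ± 0.20), DNLZ (-1.42 ± 0.42), RAB40B (-1.40 ± 0.20), DUS3L (-1.35 ± 0.19, adjusted p = 9.13e-06), PCYT2 (-1.29 ± 0.23) and MRPL58 (-1.27 ± 0.26). CDKN1A rose 3.27-fold (1.71 ± 0.20). Of neuronal genes, 10 of 26 genes rose (11 adjusted over the list alone), among them CRMP1 (1.85 ± 0.20) and SYT11 (1.62 ± 0.21). Their median was 0.40 (sets 0.46, 0.36 and 0.49, adjusted p = 4.04e-08). Of ribosome biogenesis genes, 4 of 21 genes fell (4 adjusted over the list alone), among them RRP9 (-0.90 ± 0.27) and MRTO4 (-0.70 ± 0.18). Their median was -0.19 (sets -0.23, -0.18 and -0.29, adjusted p = 0.000476). Immediate-early genes lay higher (3 of 21 genes rose, 6 adjusted over the list alone), led by IER3 (1.22 ± 0.14) and the phosphatase gene DUSP5 (1.06 ± 0.18). Their median was 0.37 (sets 0.43, 0.58 and 0.25, adjusted p = 0.000117, but 0.203 with an estimated correlation). Columnar markers lay higher only with the preset correlation (adjusted p = 0.0973 with an estimated one). IL1A (at least 3.45-fold) and the antiviral gene OASL (1.33 ± 0.21) rose. limma called 881 genes higher and 294 lower, and 1927 in all with the replicate set as a block. The count was 648 without replicate set 2, and median scaling gave 574 higher and 942 lower. Calls were lost for DNLZ (without DMSO 1, 2 or 3 or combined 2, adjusted p = 0.0691 to 0.263), RRP9 (without DMSO 1 or 2 or combined 1, 2 or 3, adjusted p = 0.0536 to 0.181) and MRTO4 (without combined 1 or DMSO 2, adjusted p = 0.0828 to 0.0952).

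In OE21, AZA alone lowered genes of the interferon response, the antiviral program that these cells carried at a high level in DMSO. The death ligand gene TNFSF10 (-1.89 ± 0.31, adjusted p = 0.00105) and the T cell chemokine gene CXCL10 (-1.74 ± 0.24, adjusted p = 0.000158) fell most, followed by SOST (at least 3.08-fold), NCALD (at least 3.08-fold), ECM2 (-1.57 ± 0.17) and CRIP2 (-1.56 ± 0.23). The rises were led by the pseudogene HTATSF1P2 (at least 2.93-fold), TLE3 (1.27 ± 0.31), WWP2 (1.17 ± 0.24), NRP2 (1.16 ± 0.20), KCNE5 (at least 2.11-fold) and SMG9 (1.005 ± 0.22). Of the interferon list, 4 of 29 genes fell (15 adjusted over the list alone), among them RSAD2 (-1.28 ± 0.22), an antiviral enzyme gene, and the interferon gene IFNB1 (at least 2.05-fold). Their median was -0.57 (sets -0.505, -0.46 and -0.73, adjusted p = 1.83e-16). Histone genes lay lower, 0 of 17 past the test and 2 adjusted over the list alone, with a median of -0.60 (sets -0.32, -0.80 and -0.36, adjusted p = 4.57e-05, but 0.331 with an estimated correlation). Immediate-early genes lay higher, 2 of 21 past the test, FOSB (0.84 ± 0.20) and DUSP5 (0.84 ± 0.18), and 4 adjusted over the list alone, with a median of 0.33 (sets 0.21, 0.48 and 0.34, adjusted p = 0.00132, but 0.303 with an estimated correlation). limma called 68 genes higher and 124 lower. Median scaling gave 11 higher and 66 lower. The count was 738 (377 higher and 361 lower) with the replicate set as a block, 0 in a fit of the OE21 arrays alone, 35 without replicate set 2, and 100 without DMSO 2, 56 without DMSO 3 and 39 without AZA 3. Calls were lost without 1 array for TLE3 (without AZA 1, 2 or 3 or DMSO 2 or 3, adjusted p = 0.0595 to 0.162), WWP2 (without AZA 3, adjusted p = 0.0872), KCNE5 (without DMSO 1, 2 or 3 or AZA 2 or 3, adjusted p = 0.0805 to 0.302), SMG9 (without AZA 2 or 3 or DMSO 3, adjusted p = 0.0747 to 0.162), FOSB (without DMSO 1, 2 or 3 or AZA 2 or 3, adjusted p = 0.051 to 0.195) and DUSP5 (without DMSO 2 or AZA 3, adjusted p = 0.0735 to 0.128). The histone list lost its call without AZA 2 (adjusted p = 0.0552).

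MS-275 alone lowered the interferon response in OE21. The interferon-induced genes MX2 (-2.57 ± 0.31, adjusted p = 2.24e-06), TRIM22 (at least 5.16-fold, adjusted p = 4.48e-07), SAMD9L (-2.01 ± 0.28), USP18 (-1.98 ± 0.26), XAF1 (-1.96 ± 0.22) and LAMP3 (-1.93 ± 0.20) fell most, MX2 5.93-fold. Of the interferon list, 20 of 29 genes fell (27 adjusted over the list alone) and 0 rose, and the interferon-inducible chemokine gene CXCL10 (-1.93 ± 0.24) fell with it. The list median was -1.17 (sets -1.26, -1.04 and -1.25, adjusted p = 3.93e-50). The largest rises were in the cornified envelope genes SPRR2B (3.23 ± 0.44, adjusted p = 1.34e-05) and SPRR2C (2.71 ± 0.39), EEF1A2 (2.49 ± 0.23), ANGPTL4 (1.97 ± 0.15), SYT11 (1.94 ± 0.21) and the interleukin-33 receptor gene IL1RL1 (1.87 ± 0.21). Of squamous differentiation genes, 2 of 21 genes rose (2 adjusted over the list alone), the members being SPRR2A (1.75 ± 0.35) and the transglutaminase gene TGM3 (1.15 ± 0.27). Their median was 0.23 (sets 0.25, 0.13 and 0.29, adjusted p = 0.0391, but 0.62 with an estimated correlation). Of immediate-early genes, 4 of 21 genes rose (5 adjusted over the list alone), among them DUSP5 (1.32 ± 0.18) and IER3 (1.08 ± 0.14). Their median was 0.25 (sets 0.16, 0.29 and 0.19, adjusted p = 0.000124, but 0.203 with an estimated correlation). The neutrophil chemokine gene CXCL8 (1.62 ± 0.20), FOXA2 (1.82 ± 0.24), TUBB2B (at least 2.89-fold) and CDKN1A (0.79 ± 0.20) also rose. limma called 262 genes higher and 176 lower with MS-275 in OE21, and 826 in all with the replicate set as a block. Median scaling gave 147 higher and 149 lower, a fit of the OE21 arrays alone 111 genes, the fit without replicate set 2 224, and the count was 259 to 284 with 1 array left out. Calls were lost for TGM3 (without MS-275 1 or DMSO 2 or 3, adjusted p = 0.0723 to 0.134) and CDKN1A (without MS-275 1, 2 or 3 or DMSO 2 or 3, adjusted p = 0.0644 to 0.137). The squamous list lost its call without MS-275 1 or 3 or DMSO 2 or 3 (adjusted p = 0.0774 to 0.596).

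Both drugs together lowered nearly the whole interferon list in OE21. Of its 29 genes 25 fell and 0 rose (26 fell adjusted over the list alone). Their median was -1.73 (sets -1.61, -1.58 and -1.66, adjusted p = 1.13e-41). The largest falls were in MX2 (-3.59 ± 0.31, adjusted p = 1.55e-09), TRIM22 (at least 5.95-fold), XAF1 (-2.54 ± 0.22), IFI35 (-2.47 ± 0.16), LAMP3 (-2.43 ± 0.20) and CXCL10 (-2.30 ± 0.24), and MX2 fell 12.1-fold. The largest rises were in MICB (2.68 ± 0.22, adjusted p = 9.17e-10), which encodes a ligand of the natural killer receptor NKG2D, SPRR2B (2.61 ± 0.44), SYT11 (2.43 ± 0.21), PTGS2 (2.32 ± 0.26), IL1RL1 (2.31 ± 0.21) and VPS37D (at least 4.68-fold). Of immediate-early genes, 11 of 21 genes rose (13 adjusted over the list alone), led by DUSP5 (2.04 ± 0.18), CCN2 (1.42 ± 0.32) and DUSP6 (1.28 ± 0.25). Their median was 0.58 (sets 0.51, 0.67 and 0.72, adjusted p = 6.9e-08, but 0.064 with an estimated correlation). Of histone genes, 5 of 17 genes fell (6 adjusted over the list alone), among them H2BC5 (-1.34 ± 0.31) and H2BC12 (-1.03 ± 0.27). Their median was -0.68 (sets -0.23, -0.74 and -0.53, adjusted p = 0.00164, but 0.493 with an estimated correlation). Of integrated stress genes, 1 of 21 genes rose and 5 fell (1 and 7 adjusted over the list alone), with the phosphatase subunit gene PPP1R15A (0.98 ± 0.18) up and CHAC1 (at least 1.85-fold) down. Their median was -0.35 (sets -0.49, -0.11 and -0.27, adjusted p = 0.0329, but 0.35 with an estimated correlation). DNA replication genes lay lower only with the preset correlation (adjusted p = 0.731 with an estimated one). The death receptor gene TNFRSF10A (0.93 ± 0.20), the survival gene MCL1 (0.75 ± 0.15) and CDKN1A (1.21 ± 0.20) rose. TNFSF10 (-2.05 ± 0.31), the chemokine gene CCL5 (-1.85 ± 0.23), LSS (-1.22 ± 0.21) and ACTA2 (-1.20 ± 0.21) fell. limma called 873 genes higher and 898 lower with both drugs in OE21, and 2996 in all with the replicate set as a block. Median scaling gave 420 higher and 1017 lower, a fit of the OE21 arrays alone 746 genes, and the count was 964 without combined 3. Calls were lost for CCN2 (without combined 3, adjusted p = 0.0627) and H2BC12 (without combined 2, adjusted p = 0.0966). The histone list lost its call without combined 2 (adjusted p = 0.124) and the integrated stress list without DMSO 1 or combined 1 (adjusted p = 0.0865 to 0.117).

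**Figure D1:**
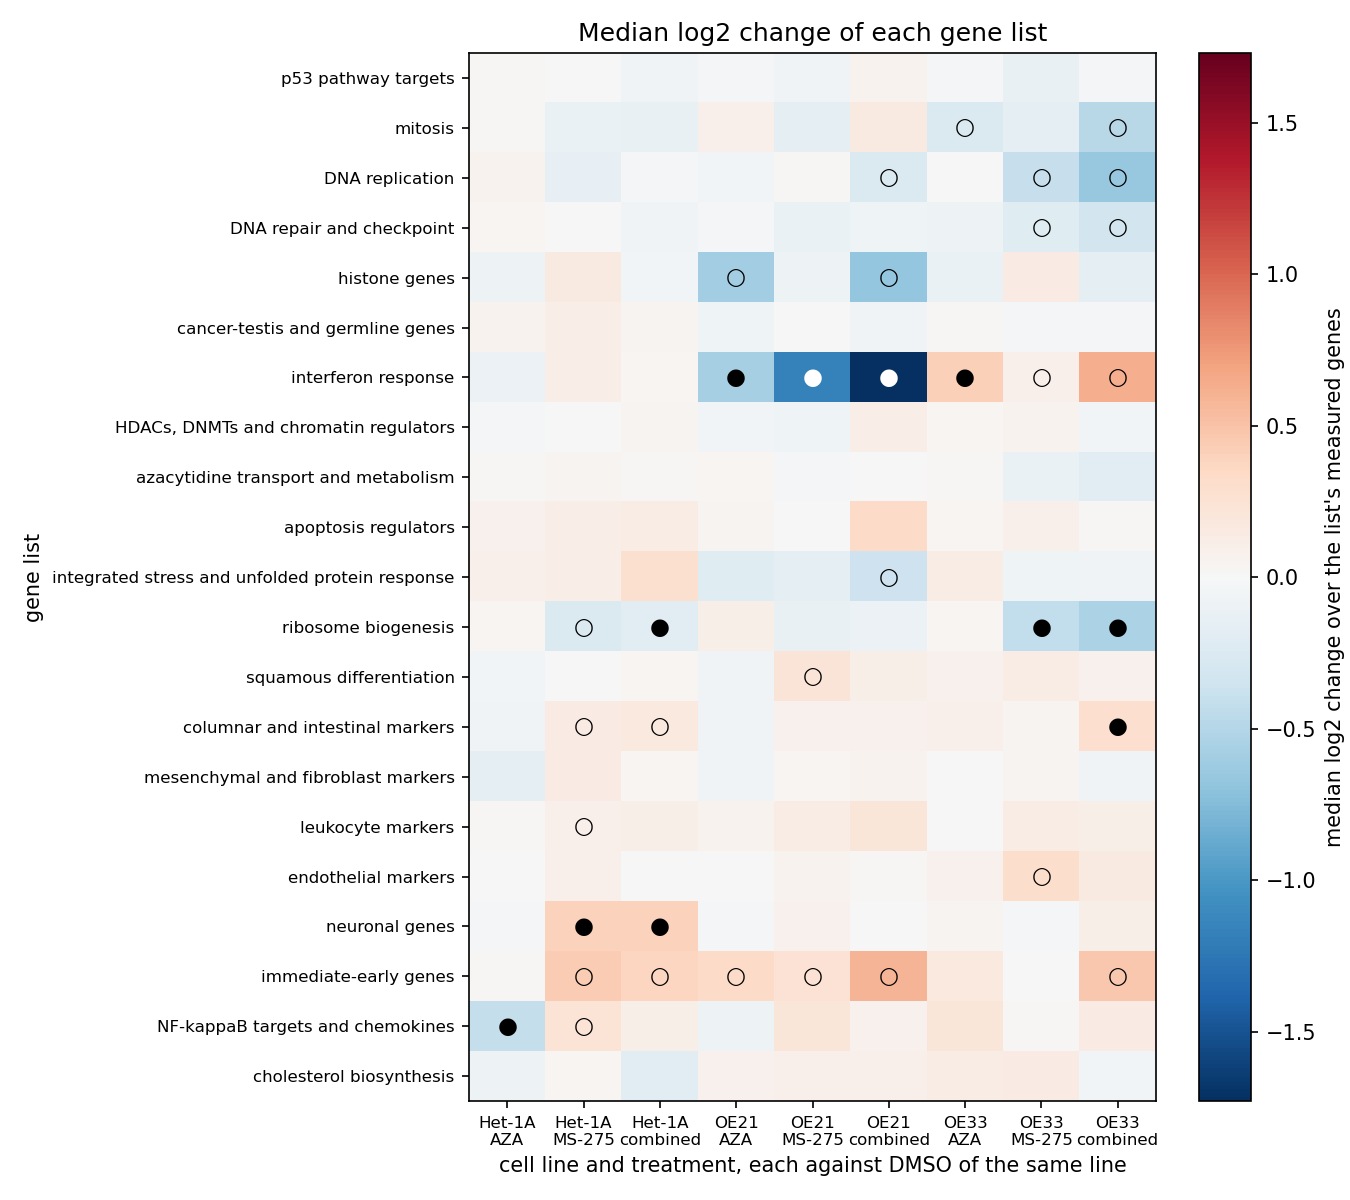
Median log2 change of each gene list (vertical axis) in the 9 drug comparisons (horizontal axis), from blue for lower to red for higher. A filled circle marks a list called at an adjusted p under 0.05 with both the preset and the estimated correlation and an open circle one called only with the preset correlation, and the interferon list runs from -1.73 with both drugs in OE21 to 0.63 with both drugs in OE33.

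In OE33, AZA moved interferon genes upward, where they had moved downward in OE21, a difference that was not tested between the tumor lines themselves. The interferon-inducible genes GBP4 (1.64 ± 0.25, adjusted p = 0.000511), UBD (1.53 ± 0.29) and GBP2 (1.44 ± 0.24) were among the largest rises, with the arginine synthesis gene ASS1 (1.46 ± 0.16, adjusted p = 7.37e-06), the pseudogene HTATSF1P2 (at least 2.78-fold) and the stress cytokine gene GDF15 (1.40 ± 0.19). The largest falls were in ABCA1 (-1.59 ± 0.29), ANXA10 (-1.40 ± 0.28), NT5E (-1.32 ± 0.17), CALB2 (-1.31 ± 0.22), SERPINE2 (-1.30 ± 0.18) and GRPR (-1.20 ± 0.20). ASS1 rose 2.74-fold and NT5E fell 2.49-fold (adjusted p = 5.95e-05). Of the interferon list, 2 of 29 genes rose (7 adjusted over the list alone), the members being OAS2 (at least 2.35-fold) and HERC5 (0.71 ± 0.15). Their median was 0.41 (sets 0.41, 0.31 and 0.58, adjusted p = 5.35e-13). Mitosis genes lay lower with 0 of 24 past the test, also adjusted over the list alone. Their median was -0.25 (sets -0.16, -0.26 and -0.34, adjusted p = 4.89e-08, but 0.119 with an estimated correlation). limma called 30 genes higher and 25 lower, and median scaling gave 40 higher and 11 lower. The count was 174 with the replicate set as a block, 16 in a fit of the OE33 arrays alone, 27 without replicate set 2, and 29 without DMSO 3 and 25 without AZA 3. Calls were lost without 1 array for UBD (without DMSO 2 or AZA 3, adjusted p = 0.0726 to 0.106), HTATSF1P2 (without DMSO 1 or AZA 3, adjusted p = 0.0794 to 0.145), ABCA1 (without AZA 3, adjusted p = 0.103), ANXA10 (without DMSO 2 or 3 or AZA 3, adjusted p = 0.0686 to 0.103), OAS2 (without DMSO 3 or AZA 3, adjusted p = 0.0561 to 0.0653) and HERC5 (without DMSO 1, 2 or 3 or AZA 3, adjusted p = 0.0619 to 0.128).

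MS-275 gave large rises in OE33. The beta-tubulin gene TUBB2B (at least 13.2-fold, adjusted p = 1.16e-14), CRIP2 (at least 12.3-fold, adjusted p = 3.02e-13), TMEM98 (3.60 ± 0.19), the elongation factor gene TCEA3 (at least 8.04-fold), the ribonuclease gene angiogenin, ANG (2.98 ± 0.31), and NDRG4 (2.89 ± 0.16) rose most. The largest falls were in the stress transcription factor gene ATF5 (-2.17 ± 0.20, adjusted p = 1.3e-09), STMN3 (-2.01 ± 0.20), LANCL2 (at least 3.95-fold), DUS3L (-1.72 ± 0.19), C1QTNF6 (-1.70 ± 0.24) and CCDC9B (-1.67 ± 0.32). Of ribosome biogenesis genes, 5 of 21 genes fell (6 adjusted over the list alone), among them BYSL (-0.79 ± 0.14) and PPAN (-0.88 ± 0.24). Their median was -0.42 (sets -0.47, -0.54 and -0.29, adjusted p = 6.87e-05). Of DNA replication genes, 4 of 22 genes fell (11 adjusted over the list alone), among them CDT1 (-0.91 ± 0.23) and CDC45 (-0.86 ± 0.23), which act in origin licensing and firing. Their median was -0.39 (sets -0.31, -0.77 and -0.27, adjusted p = 5.61e-05, but 0.493 with an estimated correlation). Of DNA repair genes, 2 of 16 genes fell (4 adjusted over the list alone), the members being RAD54L (-0.98 ± 0.18) and RAD51AP1 (-0.80 ± 0.18) of homologous recombination. Their median was -0.21 (sets -0.20, -0.26 and -0.21, adjusted p = 0.0215, but 0.336 with an estimated correlation). The interferon list was mixed, and 9 of 29 genes rose and 2 fell (9 and 4 adjusted over the list alone), with IFI6 (1.81 ± 0.31), EPSTI1 (1.60 ± 0.18) and HERC5 (1.34 ± 0.15) up. Their median was 0.094 (sets 0.081, -0.036 and 0.036, adjusted p = 0.0456, but 0.639 with an estimated correlation), or -0.043 under median scaling. Endothelial markers lay higher (2 of 8 genes rose, 2 adjusted over the list alone), the members being ESAM (1.997 ± 0.16) and EGFL7 (0.85 ± 0.23), and the adjusted p with the replicate set as a block was 0.0546. Their median was 0.31 (sets 0.17, 0.76 and 0.082, adjusted p = 0.0329, but 0.0973 with an estimated correlation). The serine synthesis gene PHGDH (2.47 ± 0.23), the squamous genes SPRR1A (1.84 ± 0.27) and SPRR3 (1.61 ± 0.20), FOXA2 (1.84 ± 0.24), CDX2 (1.34 ± 0.18), CD14 (1.65 ± 0.21), the neuronal gene MAP2 (at least 2.86-fold) and CDKN1A (0.89 ± 0.20) rose. The immediate-early gene FOSL1 (-1.36 ± 0.17) and CFLAR (-1.03 ± 0.18) fell. limma called 1038 genes higher and 814 lower with MS-275 in OE33, of which 452 and 107 changed at least 2-fold. With the replicate set as a block 1476 higher and 1564 lower were called and median scaling gave 760 higher and 879 lower. The count was 1073 without replicate set 2 and 1233 without DMSO 2. Calls were lost without 1 array for PPAN (without MS-275 3, adjusted p = 0.088), CDT1 (without MS-275 1 or DMSO 2, adjusted p = 0.0587 to 0.0608), CDC45 (without DMSO 2, adjusted p = 0.11) and EGFL7 (without DMSO 2 or MS-275 2, adjusted p = 0.0693 to 0.0756). The interferon list lost its call without MS-275 1 or 2 or DMSO 2 or 3 (adjusted p = 0.0501 to 0.0632) and the endothelial list without DMSO 2 or 3 or MS-275 2 (adjusted p = 0.0589 to 0.101).

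With both drugs OE33 gave the most calls of the 9 drug comparisons. TMEM98 (4.08 ± 0.19, adjusted p = 5.95e-16), CRIP2 (at least 13.9-fold), TUBB2B (at least 13.3-fold), TCEA3 (at least 13.5-fold), PLA2G10 (3.63 ± 0.41) and GBP2 (3.47 ± 0.24, adjusted p = 2.57e-12) rose most. The largest falls were in ANXA10 (-2.63 ± 0.28, adjusted p = 2.28e-08), the long noncoding RNA gene MANCR (-2.34 ± 0.24), STMN3 (-2.09 ± 0.20), ATF5 (-1.997 ± 0.20), GRPR (-1.98 ± 0.20) and DUS3L (-1.69 ± 0.19). Of mitosis genes, 8 of 24 genes fell (13 adjusted over the list alone), led by the kinase gene PLK1 (-1.60 ± 0.30) and the cyclin gene CCNB1 (-1.28 ± 0.21). Their median was -0.48 (sets -0.30, -0.60 and -0.58, adjusted p = 2.11e-06, but 0.181 with an estimated correlation). Of DNA replication genes, 11 of 22 genes fell (16 adjusted over the list alone), with the ribonucleotide reductase gene RRM2 (-1.33 ± 0.33) and CDC45 (-1.07 ± 0.23). Their median was -0.65 (sets -0.32, -0.69 and -0.77, adjusted p = 3.25e-07, but 0.343 with an estimated correlation). Of DNA repair genes, 4 of 16 genes fell (6 adjusted over the list alone), with RAD51AP1 (-1.12 ± 0.18). Their median was -0.32 (sets -0.24, -0.37 and -0.55, adjusted p = 0.00132, but 0.172 with an estimated correlation). Of ribosome biogenesis genes, 8 of 21 genes fell (13 adjusted over the list alone), with PPAN (-1.13 ± 0.24) and MRTO4 (-0.89 ± 0.18). Their median was -0.55 (sets -0.45, -0.73 and -0.54, adjusted p = 2.51e-06). Of the interferon list, 12 of 29 genes rose (14 adjusted over the list alone) and 0 fell, led by EPSTI1 (2.34 ± 0.18), HERC5 (2.28 ± 0.15), IFI6 (2.04 ± 0.31) and MX2 (at least 3.68-fold). Their median was 0.63 (sets 0.29, 0.40 and 1.04, adjusted p = 2.19e-08, but 0.0973 with an estimated correlation). Of columnar markers, 6 of 20 genes rose (6 adjusted over the list alone), with FOXA2 (1.82 ± 0.24), MUC1 (1.68 ± 0.23) and AGR2 (1.41 ± 0.27). Their median was 0.29 (sets 0.44, 0.32 and 0.20, adjusted p = 0.00266). Immediate-early genes were called only with the preset correlation (adjusted p = 0.561 with an estimated one), CCN2 (1.57 ± 0.32) rising and FOSL1 (-1.40 ± 0.17) falling. TNFSF10 (at least 3.27-fold), the BH3-only gene BMF (at least 1.96-fold), SNAI2 (1.33 ± 0.23), CXCL8 (1.57 ± 0.20) and CDKN1A (1.42 ± 0.20) rose. limma called 1446 genes higher and 1124 lower with both drugs in OE33, of which 645 and 166 changed at least 2-fold, and 1904 higher and 1933 lower with the replicate set as a block. Calls were lost without 1 array for RRM2 (without combined 3, adjusted p = 0.101).

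**Figure D2:**
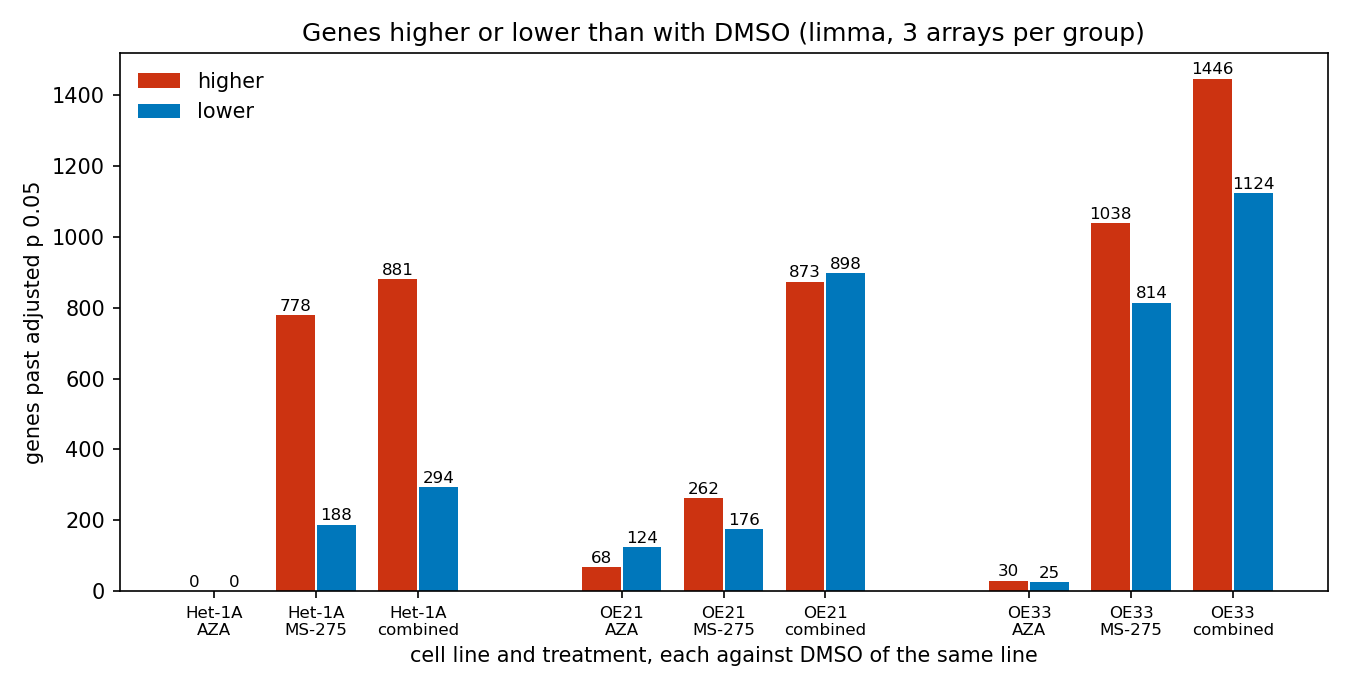
Number of genes called higher (red, left bars) and lower (blue, right bars) at an adjusted p under 0.05 in limma, for each drug against DMSO in each cell line. The counts run from 0 with AZA in Het-1A to 1446 higher and 1124 lower with both drugs in OE33.

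Of class I HDAC and DNMT genes HDAC8 alone passed the test, rising in OE33 with MS-275 (0.87 ± 0.25). Some genes of azacytidine handling passed it. HDAC1, HDAC2, HDAC3, DNMT1, DNMT3A, DNMT3B and the nucleoside transporter gene SLC29A1 passed the test in none of the 9 drug comparisons. Outside class I, HDAC6 fell in OE21 with MS-275 (-0.82 ± 0.22) and HDAC9 in OE33 (-0.86 ± 0.28, but 0.34 under median scaling). The uridine-cytidine kinase gene UCK2, which activates azacytidine, rose in OE21 with both drugs (0.38 ± 0.12) and fell in OE33 with MS-275 (-0.55 ± 0.12) and with both (-0.44 ± 0.12). The cytidine deaminase gene CDA, which inactivates it, rose in OE33 with MS-275 (1.36 ± 0.25) and with both (1.07 ± 0.25), where the deaminase gene DCTD fell (-0.68 ± 0.17 and -0.55 ± 0.17). SLC29A2 rose in Het-1A with both drugs as well (at least 2.57-fold). With MS-275, calls were lost in OE21 for HDAC6 (without DMSO 1, 2 or 3 or MS-275 1 or 2, adjusted p = 0.0519 to 0.316) and in OE33 for HDAC8 (without MS-275 1 or 2 or DMSO 3, adjusted p = 0.0776 to 0.144), HDAC9 (without MS-275 1 or 3 or DMSO 2 or 3, adjusted p = 0.0992 to 0.301) and DCTD (without DMSO 2, adjusted p = 0.0716), and with both drugs in OE21 for UCK2 (without DMSO 1 or 3 or combined 1 or 3, adjusted p = 0.0776 to 0.236) and in OE33 for UCK2 (without DMSO 1 or combined 3, adjusted p = 0.0663 to 0.0875) and DCTD (without DMSO 2 or combined 3, adjusted p = 0.0798 to 0.169). Among lists never called in a drug comparison, the medians ranged from -0.13 to 0.061 for p53 targets, from -0.08 to 0.12 for cancer-testis and germline genes, from -0.072 to 0.11 for HDACs, DNMTs and chromatin regulators, from -0.18 to 0.049 for azacytidine transport and metabolism, from -0.0063 to 0.33 for apoptosis regulators, from -0.16 to 0.14 for mesenchymal markers and from -0.19 to 0.14 for cholesterol biosynthesis. The smallest adjusted p among them was 0.0713, for mesenchymal markers. Median, mean and test differed in sign in 32 of the 189 list tests of the drug comparisons, of which 0 were called.

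Adding AZA to MS-275 changed no gene past the test in Het-1A and changed genes in both tumor lines, a difference between lines that was not tested. In OE21, HTATSF1P2 (at least 3.1-fold, adjusted p = 0.00158), FAM83B (1.33 ± 0.27), SMG9 (1.27 ± 0.22) and MON1A (1.25 ± 0.21) were higher with both drugs than with MS-275 alone. The Wnt ligand gene WNT4 (at least 2.84-fold, adjusted p = 2.71e-05), ECM2 (at least 2.99-fold), PADI3 (at least 2.91-fold) and B4GALNT1 (-1.49 ± 0.26) were lower. In OE33, UBD (2.32 ± 0.29, adjusted p = 8.43e-05) and the guanylate-binding genes GBP4 (1.86 ± 0.25), GBP1 (1.75 ± 0.27) and GBP2 (1.72 ± 0.24) were higher. There CPA4 (-1.55 ± 0.24), NTSR1 (-1.20 ± 0.23), ANXA10 (-1.19 ± 0.28) and LMO7 (at least 2.07-fold) were lower. limma called 0 genes in Het-1A, 312 higher and 314 lower in OE21, and 95 higher and 33 lower in OE33. In Het-1A 492 genes had an unadjusted p under 0.05, again fewer than the 845 expected with no effect. With the replicate set as a block the counts were 0, 1588 and 362, and in fits of each line alone they were 0. Without replicate set 2 they were 205 in OE21 and 25 in OE33. Median scaling gave 78 higher and 140 lower in OE21 and 72 higher and 7 lower in OE33. Leaving out 1 array gave 1 without combined 2 and 1 without MS-275 3 in Het-1A. In OE21 it gave 50 to 1201 and in OE33 22 to 170, both lowest without combined 3. OE21 calls were lost for FAM83B (without combined 3, adjusted p = 0.112) and PADI3 (without combined 3, adjusted p = 0.0663). OE33 calls were lost for NTSR1 (without MS-275 3 or combined 3, adjusted p = 0.0821 to 0.159), ANXA10 (without MS-275 1, 2 or 3 or combined 2 or 3, adjusted p = 0.0514 to 0.353) and LMO7 (without MS-275 1 or 3 or combined 3, adjusted p = 0.0644 to 0.125).

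Adding MS-275 to AZA moved many of the genes named with MS-275 alone. Het-1A had higher HLA-DMB (at least 9.73-fold), PTGS2 (at least 6.03-fold), IL24 (2.48 ± 0.24) and CGN (2.47 ± 0.19, adjusted p = 2.79e-10), and lower ZFHX4-AS1 (-1.29 ± 0.17), HK2 (-1.29 ± 0.22), LANCL2 (-1.25 ± 0.14) and DUS3L (-1.21 ± 0.19). OE21 had higher SPRR2B (2.80 ± 0.44), SPRR2C (2.29 ± 0.39), SYT11 (2.08 ± 0.21) and BSPRY (1.91 ± 0.19), and lower MX2 (-2.44 ± 0.31), IFI44L (-1.85 ± 0.26), XAF1 (-1.81 ± 0.22) and MX1 (-1.75 ± 0.24, adjusted p = 1.79e-05). OE33 had higher TMEM98 (4.08 ± 0.19), TUBB2B (at least 13.6-fold), CRIP2 (at least 12.8-fold) and EEF1A2 (3.48 ± 0.23, adjusted p = 1.15e-12), and lower ATF5 (-1.95 ± 0.20), STMN3 (-1.77 ± 0.20), MPDU1 (-1.76 ± 0.18) and AVEN (-1.55 ± 0.22). limma called 830 higher and 254 lower in Het-1A, 265 and 202 in OE21, and 1267 and 878 in OE33. With the replicate set as a block these came to 1813, 981 and 3239, and median scaling gave 590 higher and 404 lower in Het-1A and 940 higher and 1250 lower in OE33. In OE21 the count was 269 under median scaling, 81 in a fit of the OE21 arrays alone, 211 without replicate set 2 (549 in Het-1A), and 294 without AZA 1, 306 without AZA 2 and 304 without combined 3. Whether both drugs departed from the sum of the single drugs was tested per gene, and limma called 0 genes in each line, with 277 in Het-1A, 534 in OE21 and 768 in OE33 at an unadjusted p under 0.05. With the block the counts were 0, 0 and 4, without replicate set 2 OE33 had 1, and leaving out 1 array gave 0 to 2 in OE21 and 0 to 1 in OE33.

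The response of OE21 differed from that of Het-1A in genes that included most of the interferon list. No size is given for a gene with any of the 4 groups not detected on all of its arrays. HLA-DMB lay at background in OE21 in both groups, and SPRR2B, SPRR2C, SPRR2A, KPRP, IL1RL1, ECM2, WNT4 and IFNB1 did in Het-1A, so the response of that line could not be read. With MS-275, LAMP3 (-3.06 ± 0.28), SAMD9L (-2.66 ± 0.39) and HLA-DMB and CYP4F22 (adjusted p = 4.27e-08 to 9.49e-06) responded lower in OE21, and SPRR2B, SPRR2C, SPRR2A and KPRP (adjusted p = 0.00445 to 0.0493) higher. Of the interferon list, 18 of 29 genes responded lower (26 adjusted over the list alone). Their median was -1.46 (sets -1.36, -1.32 and -1.47, adjusted p = 1.13e-41). With both drugs the lowest were LAMP3 (-3.53 ± 0.28), MX2 (-3.33 ± 0.43), IFI44L (-2.89 ± 0.37) and HLA-DMB (adjusted p = 1.57e-08). The highest were CFAP141 (2.18 ± 0.34) and SPRR2B, VPS37D and IL1RL1 (adjusted p = 2.92e-05 to 0.0127). To both drugs 22 of 29 interferon genes responded lower, 25 adjusted over the list alone, with a median of -1.85 (sets -1.74, -1.74 and -1.79, adjusted p = 9.69e-39). Neuronal genes responded lower to MS-275 in 4 of 26 cases, 8 adjusted over the list alone, with a median of -0.28 (sets -0.36, -0.42 and -0.58, adjusted p = 6.21e-05). To both drugs 6 of 26 did, 8 lower and 1 higher adjusted over the list alone, with a median of -0.33 (sets -0.38, -0.25 and -0.53, adjusted p = 0.000659). Integrated stress genes responded lower to both drugs in 4 of 21 cases and higher in 1, 10 and 1 adjusted over the list alone, with a median of -0.56 (sets -0.76, -0.54 and -0.59, adjusted p = 0.00071, but 0.137 with an estimated correlation). With AZA, ASS1 (-1.21 ± 0.23) and ECM2, CXCL10 and WNT4 (adjusted p = 0.000351 to 0.0391) responded lower. So did the interferon list, with 1 of 29 genes past the test, IFNB1 (adjusted p = 0.0142), 7 adjusted over the list alone, and a median of -0.44 (sets -0.41, -0.42 and -0.72, adjusted p = 9.75e-11, but 0.0542 with an estimated correlation). Other lists were called only with the preset correlation, histone, integrated stress, immediate-early and NF-kappaB genes with AZA, integrated stress genes with MS-275 and mitosis and ribosome biogenesis genes with both drugs (adjusted p = 0.219 to 0.594 with an estimated correlation). limma called 0 higher and 6 lower responses to AZA in OE21 against Het-1A, 30 and 244 to MS-275, and 192 and 594 to both drugs. With the replicate set as a block the counts were 10, 479 and 1620, and without replicate set 2 0, 119 and 393. For AZA the count was 2 in a fit of the 2 lines alone and 1 to 12 with 1 array left out. For both drugs it was 501 without OE21 combined 3. Calls with AZA were lost for CXCL10 (without any array but Het-1A AZA 1 and 3 and OE21 AZA 1, adjusted p = 0.054 to 0.311), WNT4 (without Het-1A DMSO 1 or 3, Het-1A AZA 2, OE21 DMSO 2 or 3 or OE21 AZA 3, adjusted p = 0.055 to 0.0871), ASS1 (without any array but Het-1A AZA 3 and OE21 AZA 1 and 2, adjusted p = 0.0601 to 0.311) and IFNB1 (without Het-1A DMSO 1 or 2, Het-1A AZA 2 or OE21 DMSO 2, adjusted p = 0.057 to 0.0627). With MS-275 they were lost for SPRR2A (without any array but OE21 DMSO 1 and OE21 MS-275 2, adjusted p = 0.0739 to 0.164) and KPRP (without any array but Het-1A DMSO 3, OE21 DMSO 1 and OE21 MS-275 2 and 3, adjusted p = 0.052 to 0.138), and with both drugs for SPRR2B (without OE21 DMSO 2, adjusted p = 0.055).

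The response of OE33 differed from that of Het-1A in neuronal, interferon and NF-kappaB target genes. Sizes are left out as for OE21, and the response could not be read in OE33 for IL24, HPCAL4, CYP4F22 and CNTNAP2 or in Het-1A for PLA2G10 and NES. With MS-275, TMEM98 (2.94 ± 0.27) and PLA2G10, CRIP2 and NES (adjusted p = 2.87e-07 to 0.00102) responded higher in OE33, and IL24, HPCAL4, CYP4F22 and CNTNAP2 (adjusted p = 8.46e-08 to 2.1e-05) lower. Neuronal genes responded lower in 7 of 26 cases and higher in 1, 9 and 3 adjusted over the list alone, with a median of -0.40 (sets -0.33, -0.31 and -0.71, adjusted p = 0.000366). NF-kappaB targets responded lower in 4 of 19 cases, 7 adjusted over the list alone, with a median of -0.35 (sets -0.51, -0.47 and -0.74, adjusted p = 0.000198, but 0.063 with an estimated correlation). Immediate-early genes did so in 5 of 21 cases, 5 adjusted over the list alone, with a median of -0.22 (sets -0.30, -0.25 and -0.23, adjusted p = 0.00149, but 0.304 with an estimated correlation). With both drugs, TMEM98 (3.45 ± 0.27) and PLA2G10, UBD and CRIP2 (adjusted p = 1.6e-08 to 4.81e-05) responded higher, and ANXA10 (-2.80 ± 0.40) and HPCAL4, MANCR and IL24 (adjusted p = 1.15e-07 to 1.16e-05) lower. Interferon genes responded higher to both drugs in 7 of 29 cases, 10 adjusted over the list alone, with a median of 0.38 (sets 0.37, 0.13 and 0.79, adjusted p = 7.11e-07, but 0.154 with an estimated correlation). DNA repair genes responded lower in 3 of 16 cases, 7 adjusted over the list alone, with a median of -0.57 (sets -0.38, -0.30 and -0.77, adjusted p = 0.000269, but 0.12 with an estimated correlation). With AZA, interferon genes lay higher than in Het-1A with 0 of 29 past the test, 4 adjusted over the list alone, and a median of 0.55 (sets 0.46, 0.45 and 0.57, adjusted p = 1.65e-12). NF-kappaB targets lay higher too with 0 of 19 past the test, 3 adjusted over the list alone, and a median of 0.54 (sets 0.25, 0.49 and 0.55, adjusted p = 2.22e-07). Other lists were called only with the preset correlation, mitosis, squamous and cholesterol genes with AZA, DNA repair genes with MS-275 and mitosis, DNA replication and neuronal genes with both drugs (adjusted p = 0.164 to 0.592 with an estimated correlation). Single genes with a higher response to AZA were GDF15 (1.66 ± 0.27, adjusted p = 0.00944), ASS1 (1.35 ± 0.23) and UBD and SNCAIP (adjusted p = 0.0355 to 0.0376), and SERPINE2 (-1.45 ± 0.26), GRPR (adjusted p = 0.0376), NT5E (-1.20 ± 0.24) and MARCHF4 (-1.14 ± 0.22) responded lower. limma called 5 higher and 5 lower responses to AZA in OE33 against Het-1A, 210 and 297 to MS-275, and 399 and 381 to both drugs, and with the replicate set as a block 26, 840 and 1451 in all. Without replicate set 2 the counts were 0, 191 and 360, and a fit of the 2 lines alone gave 6 for AZA. Median scaling gave 3 higher and 0 lower for AZA and 516 higher and 219 lower for both drugs. For AZA the count was 0 to 9 with 1 array left out. Calls were lost for UBD (without any array but OE33 AZA 2, adjusted p = 0.057 to 0.179), GDF15 (without Het-1A DMSO 3, adjusted p = 0.0506), SNCAIP (without any array but Het-1A DMSO 1, adjusted p = 0.0822 to 0.207), ASS1 (without OE33 AZA 1, Het-1A DMSO 2 or 3, Het-1A AZA 2 or 3 or OE33 DMSO 3, adjusted p = 0.0505 to 0.0754), SERPINE2 (without any array but Het-1A AZA 1, OE33 DMSO 1 and OE33 AZA 2, adjusted p = 0.0505 to 0.0954), GRPR (without any array but OE33 AZA 2, adjusted p = 0.057 to 0.191), NT5E (without any array but OE33 DMSO 1 and OE33 AZA 2, adjusted p = 0.0747 to 0.179) and MARCHF4 (without any array but OE33 AZA 2, adjusted p = 0.0515 to 0.133).

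Genes called in the same direction with MS-275 or with both drugs in several lines, which share no control arrays, were more than independent lists would give. MS-275 raised 47 genes in all 3 lines where 0.741 would be expected and lowered 10 where 0.0943 would be, and both drugs raised 100 (3.9 expected) and lowered 40 (1.04 expected). The 47 included CDKN1A, FOXA2, SYT11, EEF1A2, ANGPTL4 and CD14, and the 10 included LANCL2 and DUS3L. Het-1A and OE33 shared 271 genes higher with MS-275 (47.8 expected, one-sided Fisher's exact p = 1.31e-138) and OE21 and OE33 shared 87 (16.1 expected, p = 5.3e-41 in the same exact test). AZA raised 1 gene in both OE21 and OE33, HTATSF1P2 (0.121 expected, Fisher's exact p = 0.114), and lowered 2, MANCR and NASP (0.183 expected, Fisher's exact p = 0.0144), all named after their values were seen. Of 523 genes called with both drugs in OE21 and in OE33, 159 changed in opposite directions, 10 of them on the interferon list, and of 141 called with MS-275, 18 did, among them EPSTI1, IFIT1, OAS1 and OAS3, chosen after their values were seen. Of 6 called with AZA, ASS1, LAMP3 and RNF213 did, likewise named after their values were seen. No expected number was computed for opposite calls.

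**Figure D3:**
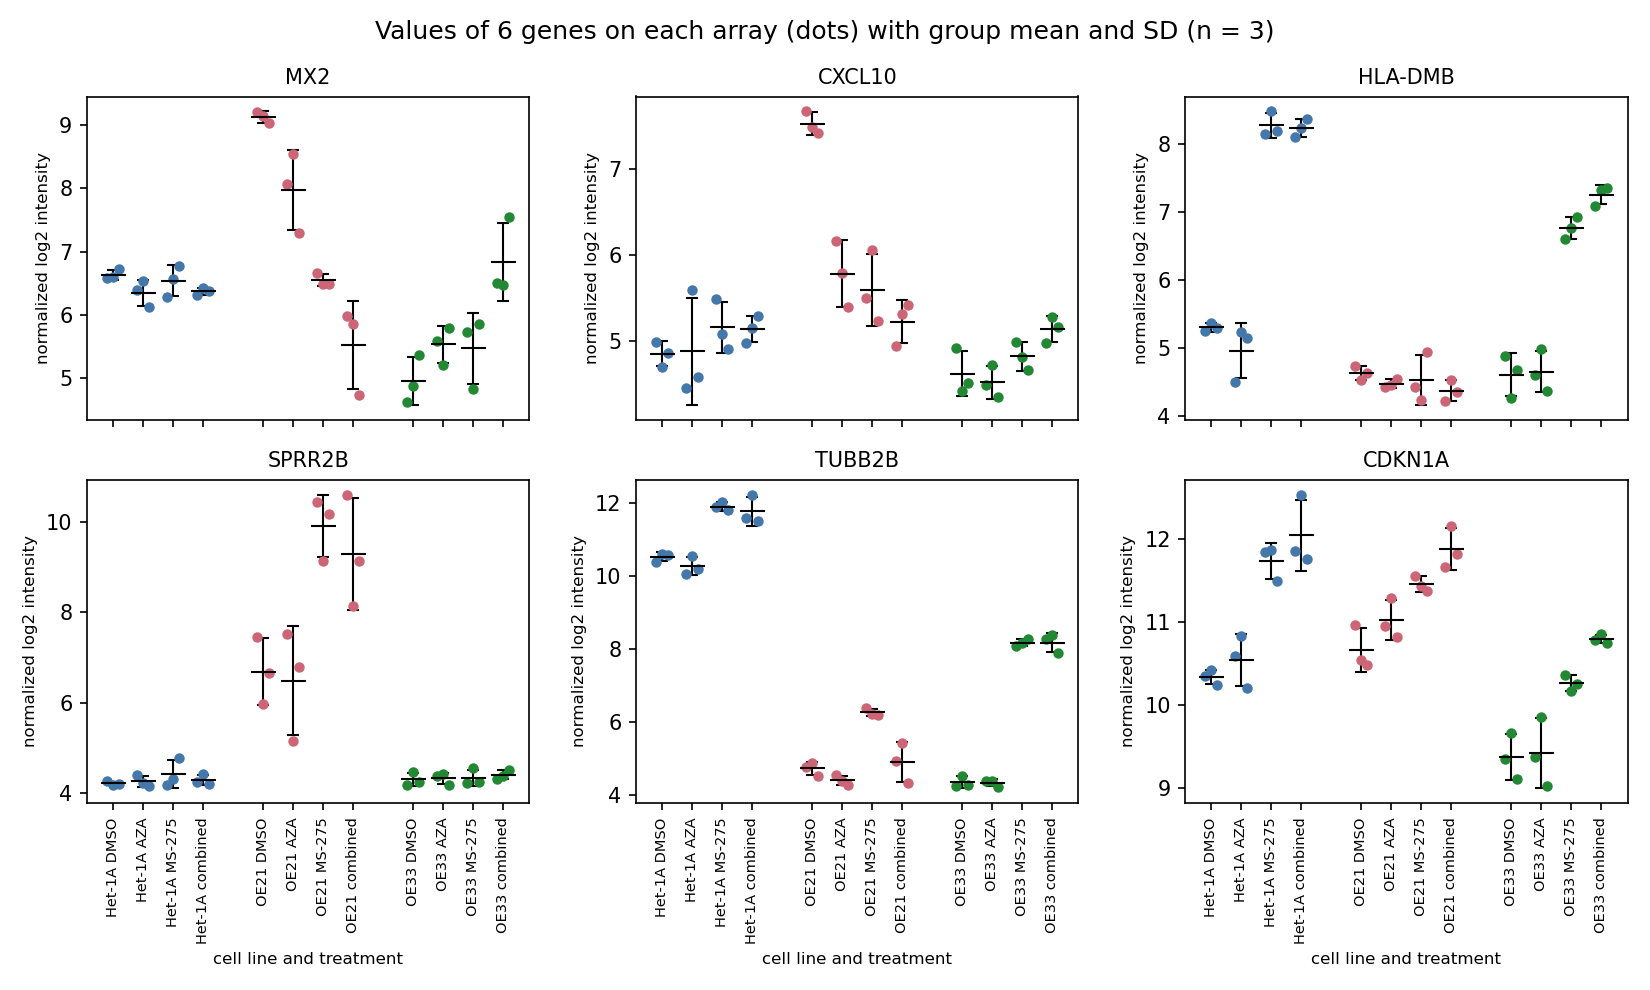
Normalized log2 intensity of 6 genes on each array (dots), with the mean and SD of each group (n = 3), for the 4 treatments of each cell line. MX2 and CXCL10 fall with MS-275 in OE21, HLA-DMB rises with MS-275 in Het-1A, SPRR2B rises with MS-275 in OE21, TUBB2B rises with MS-275 in OE33 (at least 13.2-fold), and CDKN1A rises with MS-275 in all 3 lines.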

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

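Of the tests in this part, those of the interferon list between the combination and AZA alone and without replicate set 2 were chosen after the result was seen, and so were the median change of the genes AZA changed and the rule that a value must pass the most extreme other split by more than the SD over the other splits. Responses that differed between a tumor line and Het-1A were called by limma's test of the difference itself. OE21 differed from Het-1A in 6 responses to AZA, 274 to MS-275 and 786 to both drugs, and OE33 in 10, 507 and 780.

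Other splits of the same 12 arrays do not tell whether chance can be excluded for these counts. They exchange drug and DMSO arrays within each line, and a split that turns 1 line over, wholly or in part, adds the responses of both lines instead of subtracting them, so that the response the lines share enters its count. In OE21 as many genes were called in 9 of 100 splits for AZA (6, highest other split 21), 7 for MS-275 (274, highest other 1239) and 3 for both drugs (786, highest other 860). In OE33 these were 3 for AZA (10, highest other 11), 6 for MS-275 (507, highest other 2480) and 5 for both drugs (780, highest other 1429). Splits that call several times the real count point to this structure of the samples. For departures from additivity, 100 of 100 splits called as many genes as the real 0 in each line, with up to 679 in Het-1A, 590 in OE21 and 1954 in OE33, which again is the structure of the samples.

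Comparisons of 3 arrays against 3 have 10 splits, too few for a share under 0.05. Other splits mix both groups, so a real difference lowers their counts. The real count and the highest other in Het-1A were 0 and 0 for AZA (all 10 splits as large), 966 and 1 for MS-275, 1175 and 0 for both drugs, 1084 and 1 for both against AZA and 0 and 3 for both against MS-275. In OE21 they were 192 and 1 for AZA, 438 and 1 for MS-275, 1771 and 2 for both drugs, 467 and 91 for both against AZA and 626 and 5 for both against MS-275. OE33 gave 55 and 10 for AZA, 1852 and 8 for MS-275, 2570 and 1 for both drugs, 2145 and 2 for both against AZA and 128 and 1 for both against MS-275. In DMSO the counts were 6428 and 2 for OE21 and 6503 and 1 for OE33. Among the 4 splits parting the arrays of every set, the highest other was 4.

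Interferon response genes fell in OE21 with MS-275 and with both drugs. Chance highs on the DMSO arrays are argued against by the combination against AZA alone, which uses none of them (median log2 change -1.07, lowest other split -0.52, SD over the other splits 0.371). Deviating arrays of replicate set 2 are argued against by the fit without that set (median with MS-275 -1.24, lowest other split -0.038, SD 0.0369). A fall of any genes as far above Het-1A in DMSO is argued against by matched lists, of which 0 of 10000 had a median as low with MS-275 (lowest -0.37). A response of interferon genes to HDAC inhibition in OE21 stays open as a hypothesis, found and tested on the same arrays.

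The genes that AZA changed in OE21 moved the same way when AZA was added to MS-275, which shares no array with that comparison, in 96.9% of 192 genes. That met the bound written before the result was seen, over 75% and more than any other split (highest 94.8%), but every other split keeps part of any AZA effect, and a share cannot pass 100%. Their median change in the direction of AZA alone was 0.66 against 0.40 in the highest other split, a gap slightly under the SD of 0.274, so array deviations cannot be told apart from an effect of AZA. Deviating AZA and combination arrays of set 2 are argued against by the fit without that set. There 100% of 35 genes moved the same way and the median change was 0.62. The 4 other splits are again a weak check (highest 74.3% and 0.15, SD 0.160).

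NF-kappaB targets lay lower with AZA in Het-1A although no single gene passed. They lay lower when AZA was added to MS-275 (median log2 change -0.30, lowest other split -0.16, SD 0.079). AZA and combination arrays deviated alike (20.3 and 27.9 in set 2 on the within-group axis), so shared deviations stay open. A single deviating array is argued against by the median nearest to 0 with 1 array left out (-0.31). In the comparison with DMSO itself the median of -0.42 lay past the lowest other split of -0.27 by slightly less than the SD of 0.159. Lower activity of NF-kappaB targets under AZA stays a hypothesis, found and tested on the same arrays.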

How the results depend on the processing

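The fits without replicate set 2, with array weights, and with weights and the block together were chosen after the data were seen, and the other alternatives before. Of 729 values of named genes past the test, all 729 kept direction and call with the replicate set as a block, and so did the 723 that a stricter filter left. The call ended without a change of direction for 107 under median scaling, 57 with no background correction, 58 with the submitters' processed values, 137 in fits of the compared lines alone, 199 without replicate set 2, 20 with array weights, 1 with weights and the block, 24 with no filter and 29 with every probe tested. Leaving out 1 array ended the call in 812 of 5304 fits. Of 73 list calls, 58 held with fry, which tests whether the genes of a list move one way on balance. The block ended 2 of the list calls, for endothelial markers in OE33 with MS-275 (adjusted p = 0.0546) and for neuronal genes in the difference of OE33 from Het-1A with both drugs (0.0604), and changed no other call of a list or a named gene. Further list calls were ended by median scaling (4), no background correction (6), the submitters' values (5), fits of the compared lines alone (5), the stricter filter (8), array weights (2), weights with the block (2) and leaving out replicate set 2 (7), 0 by the absence of a filter, and 79 of 600 by leaving out 1 array.

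Sizes moved by over 1.5 times for 38 of the 73 list medians with no background correction, 32 with the submitters' values, 20 under median scaling, 13 with the stricter filter, 13 without replicate set 2, 3 with array weights, 2 with weights and the block and 50 of 600 with 1 array left out. Of the 729 named values, 344 moved so far with no background correction and 300 with the submitters' values (0.70 and 0.73 times as large at the median), 24 under median scaling and 11 without replicate set 2.

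These directions turned. BRDT with both drugs in OE21 was 0.016 within replicate set 3. HDAC9 was -0.35 in OE33 against Het-1A in DMSO and 0.34 in OE33 with MS-275 under median scaling. IL1A in the difference of OE21 from Het-1A with both drugs was 0.026 with no background correction. The interferon median in OE33 with MS-275 was -0.036 within set 2 and -0.043 under median scaling. Median scaling moved the median of all genes to -0.11 for both drugs in Het-1A and to 0.12 for AZA and 0.10 for both drugs in the difference of OE33 from Het-1A.

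The counts that moved by more than 1.5 times are given per alternative, "for both" meaning both drugs and "the departure from the sum" the test of additivity. With the replicate set as a block, which rests on the pairing, Het-1A had 2 for AZA, 1569 for MS-275, 1927 for both drugs and 1813 for both against AZA. OE21 had 738 for AZA, 826 for MS-275, 2996 for both drugs, 981 for both against AZA and 1588 for both against MS-275. OE33 had 174 for AZA, 3040 for MS-275, 4 for the departure from the sum, 3239 for both against AZA and 362 for both against MS-275. The difference of OE21 from Het-1A had 10 for AZA, 479 for MS-275 and 1620 for both drugs. That of OE33 had 26 for AZA, 840 for MS-275 and 1451 for both drugs. With the block and array weights together, Het-1A had 9 for AZA, 2658 for MS-275, 3237 for both drugs, 2859 for both against AZA and 2 for both against MS-275. OE21 had 1092 for AZA, 1262 for MS-275 and 1 for the departure from the sum. OE33 had 241 for AZA, 3037 for MS-275, 10 for the departure from the sum and 251 for both against MS-275. The difference of OE21 from Het-1A had 145 for AZA, 881 for MS-275 and 1624 for both drugs. That of OE33 had 63 for AZA, 1236 for MS-275 and 1625 for both drugs. With array weights alone, Het-1A had 6 for AZA and 1771 for MS-275 and OE21 had 342 for AZA, 724 for MS-275, 1 for the departure from the sum, 271 for both against AZA and 168 for both against MS-275. OE33 had 211 for both against MS-275. The difference of OE21 from Het-1A had 25 for AZA and 546 for MS-275 and that of OE33 had 23 for AZA. Without replicate set 2, Het-1A had 531 for MS-275, 648 for both drugs and 549 for both against AZA. OE21 had 35 for AZA, 224 for MS-275, 211 for both against AZA and 205 for both against MS-275. OE33 had 27 for AZA, 1073 for MS-275, 1 for the departure from the sum and 25 for both against MS-275. The difference of OE21 from Het-1A had 0 for AZA, 119 for MS-275 and 393 for both drugs. That of OE33 had 0 for AZA, 191 for MS-275 and 360 for both drugs. In fits of the compared lines alone, OE21 had 0 for AZA, 111 for MS-275, 746 for both drugs, 81 for both against AZA and 0 for both against MS-275 and OE33 had 16 for AZA and 0 for both against MS-275. The difference of OE21 from Het-1A had 2 for AZA and that of OE33 had 6 for AZA. With no background correction, Het-1A had 2 for AZA and 1 for both against MS-275 and OE33 had 85 for AZA and 1 for the departure from the sum. OE21 had 1 for the departure from the sum and the difference of OE33 from Het-1A had 17 for AZA. Under median scaling, OE21 had 77 for AZA, 269 for both against AZA and 218 for both against MS-275 and OE33 had 79 for both against MS-275. The difference of OE33 from Het-1A had 3 for AZA. From the submitters' processed values, Het-1A had 2 for AZA and 1 for both against MS-275 and OE21 had 1 for the departure from the sum. Under the stricter filter, Het-1A had 2 for AZA and 1 for both against MS-275. With no filter, the difference of OE33 from Het-1A had 5 for AZA. With every probe tested, the difference of OE21 from Het-1A had 3 for AZA. With 1 array left out in turn, Het-1A had 0 to 4 for AZA and 0 to 1 for both against MS-275. OE21 had 39 to 194 for AZA, 259 to 284 for MS-275, 964 to 2119 for both drugs, 0 to 2 for the departure from the sum, 294 to 559 for both against AZA and 50 to 1201 for both against MS-275. OE33 had 25 to 65 for AZA, 1233 to 1684 for MS-275, 0 to 1 for the departure from the sum and 22 to 170 for both against MS-275. The difference of OE21 from Het-1A had 1 to 12 for AZA and 501 to 1018 for both drugs. That of OE33 had 0 to 9 for AZA. Fewer arrays were fitted without replicate set 2, with 1 array left out and in fits of the compared lines alone, and for the other alternatives the cause was not tested.

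Signal over background limits what could be seen, since the brightest 1% of probes began at 51.6 to 82.4 times the background level and a gene at background gives only a bound on its fold. With changes added to simulated data, the drug comparisons recovered 12% to 24% of genes changed by 0.5 on the log2 scale, 54% to 72% at 1, 88% to 98% at 1.5 and 96% to 100% at 2. The tests of additivity recovered 0% to 6%, 22% to 34%, 74% to 76% and 90% to 94% at the same sizes, so that a departure of 1 or less would mostly be missed.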

Other observations

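The tests in this part were chosen after values were seen, except that the outcome required of the MHC class II test was written before it was run.

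Some MHC class II genes rose with MS-275 in Het-1A and OE33. HLA-DMB was among the largest rises in Het-1A. A list of the other class II genes, with their assembly chaperone CD74 and their transcriptional activator CIITA, was therefore tested. In Het-1A, HLA-DMA rose with MS-275 and with both drugs (2.02 ± 0.21 and 1.96 ± 0.21), as did HLA-DPA1 (0.87 ± 0.17 and 0.64 ± 0.17) and HLA-DRA (0.74 ± 0.18 and 0.75 ± 0.18). OE33 raised HLA-DMA (2.08 ± 0.21 and 2.50 ± 0.21), HLA-DMB (at least 4.32-fold and 6.07-fold), HLA-DPA1 (at least 3.61-fold and 4.93-fold) and CD74 (0.96 ± 0.24 and 1.25 ± 0.24). The call of CD74 with MS-275 was lost without OE33 DMSO 2 or MS-275 2 (adjusted p = 0.0526 to 0.0721), and that of HLA-DRA without Het-1A MS-275 2 or 3 or combined 3 (0.0531 to 0.0813). Of the 13 genes besides HLA-DMB, 3 rose with MS-275 in Het-1A (median 0.17) and 4 in OE33 (median 0.13), and none fell. The camera p over them with MS-275 in Het-1A was 0.000947 (adjusted over 9 comparisons 0.00284, and adjusted p = 0.0277 with an estimated correlation). OE33 gave adjusted p = 0.00131 with MS-275 and 8.38e-05 with both drugs (0.0218 and 0.00791 with an estimated correlation), and Het-1A with both drugs 0.00829 (0.0455). In OE21 the list gave adjusted p = 0.983 with MS-275 and 0.740 with both drugs. A response of part of the class II genes to MS-275 in Het-1A and OE33 is a hypothesis that these values fit, and CIITA itself, detected on at most 1 array of a group, cannot be read.

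Interferon response genes moved in opposite directions in the tumor lines when AZA was added to MS-275. In OE21 the list lay lower with both drugs than with MS-275 alone (median log2 change -0.30, 5 of 29 genes lower and 0 higher, camera p = 6.7e-07, and p = 0.03 with an estimated correlation). In OE33 it lay higher (median log2 change 0.54, 7 higher and 0 lower, p = 2.13e-13, and p = 0.00231 with an estimated correlation), and Het-1A gave -0.077 (p = 0.726). The difference between the tumor lines was not tested.

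Neighbouring genes around IMMP2L were undetected together in Het-1A. Genes were ordered as in GRCh38.p14 (16879 tested genes placed), and those detected on all 24 arrays of the other lines were compared. In Het-1A 66 of 8767 such genes were detected on at most 2 of 12 arrays, and the longest run of neighbours was 3, IMMP2L, ZNF277 and IFRD1 (1, 2 and 1 arrays). Close by, CAV2 and CAPZA2 were detected on 0 arrays, PNPLA8 and ST7 on 1, CAV1 on 3 and TES on 4, while MET, DLD, LAMB1, LSM8 and ING3 were detected on all 12 arrays and DNAJB9 on 8. Of 10000 random gene orders, 38 gave a run as long, against 5743 for the longest run of 2 in OE21 and 599 for that of 3 in OE33. A stretch of the genome that is missing or silent as a whole in Het-1A may account for the run, although MET in its midst was detected, and no DNA was measured to tell loss from silencing.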
